A study of Mus musculus with 2 samples.

How the data were processed

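DamID marks the places that a chromatin protein visits by fusing it to Dam, a bacterial methyltransferase that adds a methyl group to adenine in GATC sequences. Dam expressed without a partner marks accessible DNA and serves as the background. Here the fusion carried Dnmt1, the maintenance DNA methyltransferase of mammals. Genomic DNA came from mouse embryos of the 4- to 8-cell stage, with 50 embryos injected for each of the Dnmt1-Dam and the Dam-only construct, per the series description. Per the labels' protocols, the DNA was end-repaired, ligated to Illumina adapters, amplified with 15 cycles of PCR and size-selected around 300 bp. Each group is 1 library, so no replicate spread exists.

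Per the submitters' processing notes, CASAVA and BWA were used and the genome build was mm9. The peak caller, its thresholds, the handling of duplicate and multiply mapped reads, and the total reads per library are not given in the sources used here. The deposited table lists 8226 peaks, each as 1 position on a grid of 10 bp with no width. For each peak the authors gave a signal height in the Dnmt1-Dam library and in the Dam-only library, as whole numbers. Whether these heights are raw or scaled is not stated, so they were treated as signal and not as read counts, and no counting interval was put on a single height or ratio. Every listed peak had a Dnmt1-Dam height at least 6 above and at least 2 times its Dam-only height. No Dam-only height was under 1. The table therefore holds positions selected for a higher Dnmt1-Dam height, and positions with an equal or higher Dam-only height were not analysed here.

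The deposited table also gives a location class, the CpG island context, the repeat classes and an assigned gene for each peak. The location class of 8226 of the 8226 peaks followed from the distance to the assigned gene. A peak was proximal promoter from 3 kb upstream to 1 kb downstream of the transcription start site, distal promoter from 10 kb to 3 kb upstream, gene body elsewhere inside the gene, and otherwise intergenic. A peak was counted for every repeat class named at it. Of 4903 transcript accessions, 4883 were matched to a gene by accession, gene ID or symbol in a RefSeq gene table of assembly GRCm38.p6. That gene table gave the names and also the background genes for the gene lists. A gene absent from the submitters' annotation counts in that background but could not receive a peak. The file gave no gene name for 473 peaks, and 443 of these were named by accession.

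Densities were computed per Mb of each chromosome up to its largest peak position, with exact Poisson intervals. Shares of peaks have exact Clopper-Pearson intervals, and ratios of densities have exact conditional intervals, all at 95%. These intervals cover counting error only, since peaks after PCR without molecular identifiers are not independent molecules. In all, 8 gene lists were fixed before the data were examined, as were the comparisons and the rule for named genes. Each list was compared with 10000 random lists of the same size, drawn from the 21035 genes with a curated messenger RNA accession. Members not found in this background were left out, so the imprinted list kept 47 of 55 genes and the 2-cell list 31 of 36. A list was said to stand apart outside the percentiles 2.5 to 97.5. With 1 library per group these percentiles describe these libraries, and no p-value was computed. The gene table's lengths belong to another build and matching with them was not tried, so the random lists were not matched on gene length. The density of peaks inside gene bodies, with lengths from the deposited table, is given beside the main counts. Classes of peaks were compared in the same way with 10000 random sets of peaks. These sets treat peaks as independent, which close neighbors are not.

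The named items were the 10 highest peaks by Dnmt1-Dam height, the 10 genes with the most peaks, the 4 members of each list with the highest peak (all members where a list had 5 or fewer with a peak), Dnmt1 itself and the repeat classes with the most peaks. Of the items this rule takes, 1 is not reported here. The deposited table holds no fold or score, so the Dnmt1-Dam height was used for ranking. The log2 ratio of the heights was computed with a pseudocount of 1 after scaling to the sums over the peaks. Alternatives were the peaks of height 9 or more (52.9% of the list), those of height 15 or more (8.66%), 1 peak per run of peaks no more than 1 kb apart, peaks at a Dam-only height of 1, other pseudocounts and filters, and narrower rules for assigning peaks to genes. Several planned steps need peak widths or a genome of the same build and were not run: random placement for location and repeat classes, overlap minimums and covered base pairs. Matching of lists on length over all genes was also not run, as lengths from another build were not used. Matching on length was limited to genes with a peak and was by decile of their length.

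On simulated data with 21000 genes, 71.5% of lists of 30 genes at 2 times the background rate and 99.5% of those at 3 times were placed above the upper percentile, against 4.0% of unchanged lists. All background genes had the same chance of a peak in that simulation. It does not cover lists whose genes differ from the background in length or spacing. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.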

Results

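To locate Dnmt1 on the genome of cleavage-stage mouse embryos, adenine methylation left by a Dnmt1-Dam fusion was profiled against that left by Dam alone. The 2 libraries came from 50 injected embryos each, collected at the 4- to 8-cell stage. They yielded 8226 deposited peaks, in mm9 coordinates, with 1 height per library. Close neighbors were frequent, with 448 peaks within 200 bp of the one before them. The total reads per library are not given in the sources used here, so the depth is unknown and the heights are the measure of how well each peak was covered. With 1 library per group, differences between the libraries have no replicate check.

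Dnmt1-Dam heights were low at most positions. The median was 9 (interquartile range 7 to 11), and 2206 peaks (26.8%) lay at 7, the smallest height in the list. At the upper end, 216 peaks (2.63%) reached 20 or more. The Dam-only height was 1 at 6239 peaks (75.8%) and at most 17, and since no value under 1 is listed, whether 1 also stands for 0 is unknown. The median ratio of Dnmt1-Dam to Dam-only height was 8 (interquartile range 7 to 9), a value bounded from below by the selection of the list. The smallest ratio in the list is 2, but every peak at a Dam-only height of 1 has a ratio of at least 7. The median therefore lies next to that floor. After scaling to the sums over the peaks (81171 for Dnmt1-Dam and 12018 for Dam-only) the median log2 ratio was 0.21, where 0 is the ratio of those sums. Left unscaled it was 2.17, and among the peaks of height 15 or more, which are selected by height, the scaled value was 1.05. With 1 peak kept per 1 kb run it was 0.05, with a pseudocount of 10 it was 0.10, and with height 9 or more it was 0.37.

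**Figure D1:**
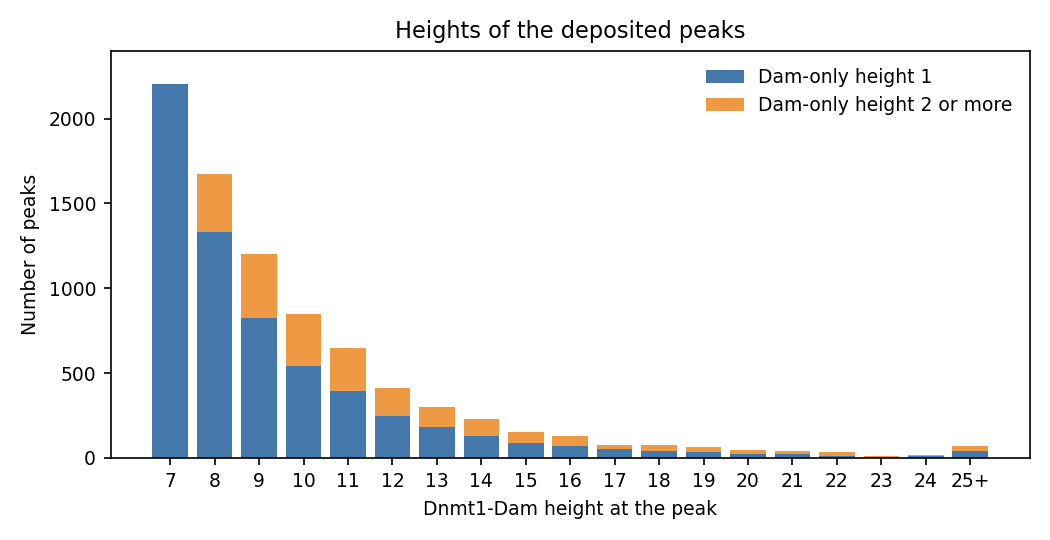
Number of peaks (y axis) at each Dnmt1-Dam height (x axis, peaks of 25 or more pooled), split by a Dam-only height of 1 (blue) or of 2 or more (orange). The list begins at a height of 7, its most frequent value with 2206 peaks, and 6239 of the 8226 peaks have a Dam-only height of 1.

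The highest peak stood far above the rest. It lay in a SINE on chromosome 5 at 106479661, in intergenic DNA assigned to Zfp326, which encodes a zinc finger protein, and had a height of 202 against 1 for Dam-only. The next, of height 66 against 1, lay on chromosome 2 at 170128281, in the shore of a CpG island assigned to Bcas1. A pair of peaks 100 bp apart followed on chromosome 11, at 103623981 (63 against 1) and 103623881 (62 against 2), at -11.6 and -11.7 kb from the start site of Wnt3 (negative distances are upstream), a secreted signaling protein of gastrulation. The peak assigned to Rpl37, a ribosomal protein gene, reached 62 against 4 on chromosome 15 at 4901291. On the same chromosome, at 11897761, a peak in LTR sequence assigned to Sub1 reached 60 against 1. The peak assigned to Rag2, an antigen receptor recombinase gene, lay at -510 kb in a SINE (chromosome 2, 100954771) and reached 54 against 1. The last of the 10 highest were inside the translational regulator gene Cpeb3 (chromosome 19, 37277201; 48 against 5), inside Zfp607 (chromosome 7, 28649501; 47 against 1) and at -10.4 kb from the ubiquitin peptidase gene Usp38 (chromosome 8, 83549181; 47 against 1). The handling of duplicate and multiply mapped reads is not given, so these heights alone do not rank sites by Dnmt1 binding. Dnmt1 itself held 1 peak, of height 16 against 1, at position 20725941 of chromosome 9. That peak lay in a SINE within the gene body, 31.4 kb downstream of the start site the file uses, in the shore of a CpG island.

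Peaks were spread over the autosomes and were sparse on the X chromosome. The autosomes held 8028 peaks, or 3.25 per Mb (95% interval 3.18 to 3.33). Chromosome 11 had the highest density at 4.17 per Mb (3.81 to 4.55) and chromosome 6 the lowest at 2.56 (2.31 to 2.83). The intervals of 4 autosomes (2, 5, 9 and 11) lay above the autosomal mean, those of 4 others (3, 6, 12 and 14) below it, and those of 11 contained it. The X chromosome held 197 peaks, or 1.18 per Mb (1.02 to 1.36), which is 0.364 times the autosomal density (0.314 to 0.419). The Y chromosome held 1 peak, of height 9 against 3, at position 2857951 and assigned to a gene of the Rbmy family, which is expressed in the male germline. The sex of the embryos is not given in the labels.

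**Figure D2:**
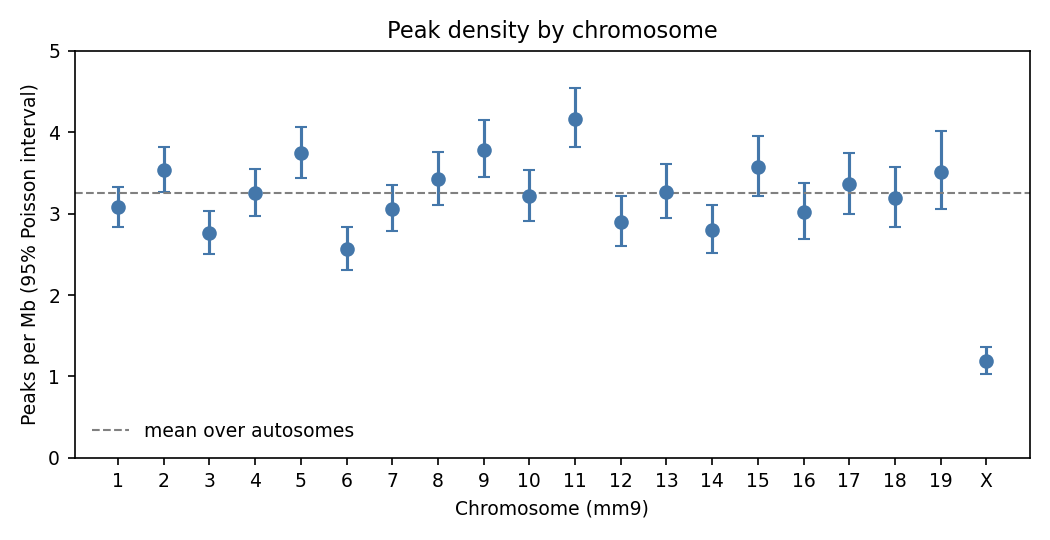
Peaks per Mb (y axis) for each autosome and X (x axis), with exact 95% Poisson intervals as bars and the autosomal mean of 3.25 as a dashed line. Autosomes range from 2.56 to 4.17 peaks per Mb, and X lies at 1.18.

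By location, 4180 peaks (50.8%, 49.7 to 51.9) were intergenic and 3492 (42.5%, 41.4 to 43.5) lay in gene bodies. Distal promoters held 335 peaks (4.07%, 3.66 to 4.52) and proximal promoters 219 (2.66%, 2.33 to 3.03). CpG islands held 46 peaks (0.559%, 0.410 to 0.745), their shores 288 (3.50%, 3.11 to 3.92) and their shelves 210 (2.55%, 2.22 to 2.92), while 7682 peaks (93.4%) had no island context. Each location class had a median height of 9 and an interquartile range of 7 to 11, so the classes could not be told apart by the median. The mean log2 height of intergenic peaks differed from that of all peaks by -0.012 (percentile 0.53 among random sets of peaks). Those sets treat peaks as independent, so the percentile may be too extreme. A genomic background for these shares was not analysed here.

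Retroelements, the transposable elements named in the title of the series, carried 2879 peaks (35.0%, 34.0 to 36.0). SINEs, which are short non-autonomous elements, were named at 1404 peaks (17.1%, 16.3 to 17.9). LTR elements, the endogenous retroviruses and their relatives, were named at 887 (10.8%, 10.1 to 11.5). LINEs, the autonomous non-LTR elements, were named at 673 (8.18%, 7.60 to 8.79). Simple repeats followed at 204 peaks (2.48%) and DNA transposons at 156 (1.90%). Satellite sequence, the tandem repeats of centromeric regions, was named at 2 peaks (0.0243%). No repeat was named at 4976 peaks (60.5%, 59.4 to 61.5). The file names repeat classes and not families, so element families such as IAP or L1 were not separated.

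The mix of retroelements differed with location. LTR elements were named at 14.0% of intergenic peaks (12.9 to 15.1) and at 7.02% of gene body peaks (6.19 to 7.91), and the intergenic share was the higher one on 19 of 19 autosomes. LINEs were named at 10.8% of intergenic (9.84 to 11.7) and 5.36% of gene body peaks (4.63 to 6.15), with the intergenic share higher on 18 of 19 autosomes. SINEs went the other way, with 15.0% of intergenic (14.0 to 16.2) and 18.4% of gene body peaks (17.1 to 19.7), and the intergenic share lower on 16 of 19 autosomes. The highest SINE share was in distal promoters, at 26.9% (22.2 to 32.0). In proximal promoters it was 19.6% (14.6 to 25.5), an interval that overlaps those of gene bodies and distal promoters. Peaks in SINEs had a median height of 9 and a mean log2 height 0.036 above all peaks (percentile 99.9). Peaks in DNA transposons and simple repeats had a median of 8, and their mean log2 heights differed from all peaks by -0.086 and -0.071 (percentiles 0.38 and 0.80). The differences of LTR elements and LINEs, -0.023 and -0.025, lay within the random sets (percentiles 4.61 and 5.54). The random sets treat peaks as independent, but heights of close neighbors correlate, so these percentiles may be too extreme. The mean log2 differences were not recalculated with 1 peak per 1 kb run. How much of the genome each class covers in each location was not analysed here, so these shares are not enrichments.

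**Figure D3:**
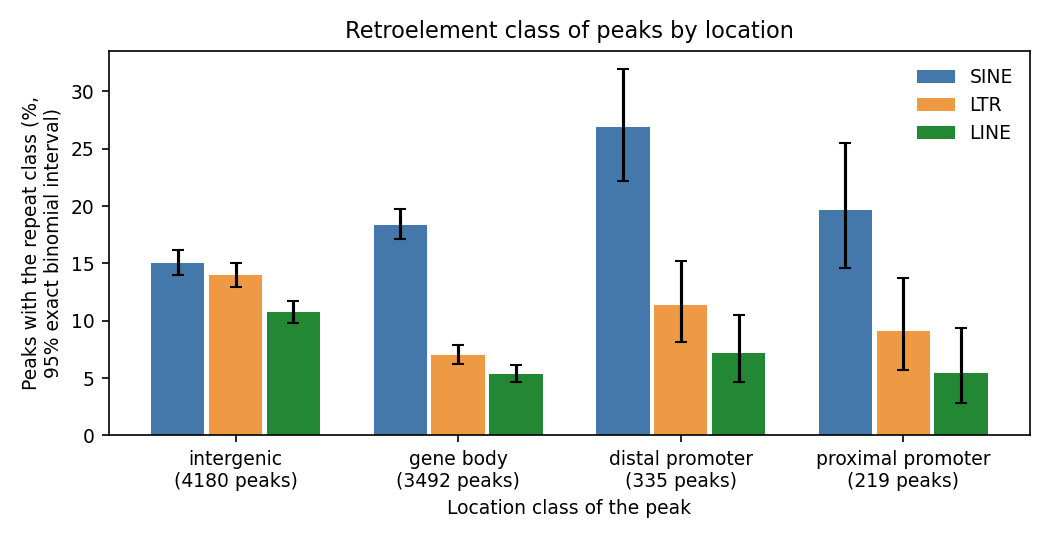
Percent of peaks (y axis) at which a SINE (blue), LTR element (orange) or LINE (green) is named, for each location class (x axis, number of peaks in brackets), with exact 95% binomial intervals. LTR elements and LINEs are named more often in intergenic peaks than in gene body peaks, and SINEs most often in distal promoters, at 26.9%.

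The assigned genes numbered 4766 of the 21035 in the background (22.7%), and 2451 genes had a peak inside the body. Of the 8 gene lists fixed in advance, 2 stood apart from random lists and 6 did not. Long genes of neuronal adhesion and synapses had a peak in 28 of 30 members, where random lists averaged 6.80 (central 95% 3 to 12; percentile 100), and 26 had one inside the body. Among them, Cdh18, a cadherin gene, had a top height of 31 against 5, outside the body. Ptprd, a receptor phosphatase gene, held 8 peaks, the highest of 26 against 1, and Ctnna2, an alpha-catenin gene, held 6, the highest of 20 against 5. The random lists were not matched on gene length, and this list is of long genes. Its count of members with a peak therefore does not by itself show a preference for these genes. The bodies of these 28 genes add up to 32.2 Mb and held 89 peaks, or 2.76 per Mb (2.22 to 3.40), an interval that contains the autosomal mean of 3.25. Against genes with a peak from the same deciles of length, whose mean was 4.02 per Mb, the direction turned (percentile 1.19). Genes without a peak did not enter that comparison. The highest decile has no upper limit, so its genes can be much shorter than these 28. The comparison therefore cannot show a lower density than in genes of equal length. With promoter peaks alone, 1 member had a peak against 0.727 expected (percentile 66.2).

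Transcription factors and receptors of the early embryonic lineages had a peak in 15 of 30 members (50.0%, 31.3 to 68.7), against 6.80 in random lists (percentile 99.9). Most of the 34 peaks lay away from the genes: 4 were inside a body, 29 were more than 10 kb outside it and 20 were more than 100 kb outside. Among all peaks, 23.1% were more than 100 kb from the assigned gene, against 58.8% in this list. The random lists were not matched on gene length or on the space between genes. The count of members with any assigned peak therefore does not by itself show a preference for these genes. Pdgfra, a receptor of primitive endoderm, had 3 peaks, the highest of 21 against 1. Klf5, a factor of the blastocyst, had a peak of 19 against 4 inside the gene, 1.35 kb from its start site. Sox7, an endoderm factor, had a peak of 16 against 1 at -15.6 kb. Sox2, a pluripotency factor, had 3 peaks, the highest of 16 against 1 at 315 kb downstream of its start site. Counting peaks inside bodies alone, 4 members had one, against 3.50 expected (percentile 63.4), and with 10 kb on either side the list was also within the random range (percentile 63.9). The body density of the 15 members was 7.15 peaks per Mb (1.95 to 18.3). Genes with a peak from the same deciles of length had a mean of 12.4. The list lay within their random range (5.23 to 20.7, percentile 8.82). Only 4 of the 15 members had a peak inside the body, and the others entered through peaks outside it.

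The 6 other lists lay within the range of random lists. Imprinted genes had a peak in 14 of 47 members (10.6 expected; percentile 87.2). These included Ppp1r9a (16 against 5, intergenic), Trappc9 (13 against 1, gene body), Igf2r, the maternally expressed clearance receptor of Igf2 (12 against 1, gene body) and Ndn (12 against 1, at -693 kb, in a LINE). None of the 47 had a peak in a promoter class, where 1.14 were expected, which is within the random range (percentile 15.8). Genes of DNA methylation and retroelement silencing had a peak in 10 of 30 members (6.80 expected; percentile 90.9), led by Dnmt1 and by Resf1 (15 against 1, gene body), Hdac2, a histone deacetylase gene (10 against 1, intergenic) and the de novo methyltransferase gene Dnmt3a (10 against 2, intergenic). Germline genes had a peak in 8 of 37 members (8.38 expected; percentile 45.6). The highest were at Mov10l1 (17 against 1, in a SINE of the gene body) and Dazl, an RNA-binding protein of germ cells (17 against 3, at -81.5 kb), followed by Stk31 (13 against 2, in a SINE) and Spata16 (10 against 1, intergenic).

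Genes of adult tissues had a peak in 8 of 30 members (6.80 expected; percentile 70.9), with Rbfox3, a neuronal splicing factor gene, at 20 against 1, Col2a1, a cartilage collagen gene, at 17 against 1, Alb, the albumin gene, at 14 against 1 and Mbp, a myelin gene, at 13 against 1. Genes of the 2-cell stage had a peak in 5 of 31 members (7.02 expected; percentile 20.3). These were Dppa4 (14 against 4, in an LTR element at -867 kb), Zfp352 (10 against 2), Eif1a (9 against 1, in the proximal promoter), Pramel6 (9 against 3, in LTR sequence) and Pramel7 (7 against 1). None had a peak inside the body, against 3.61 expected, which is outside the random range (percentile 1.14). The random lists were not matched on length. The 5 members with a peak have 0.0357 Mb of body in all, and the range of length-matched genes with a peak begins at 0 (0 to 87.8 peaks per Mb), so that comparison cannot show a lower value. Housekeeping genes had a peak in 3 of 25 members (5.66 expected; percentile 10.2), namely Pgk1 (10 against 1, in a SINE of the gene body), Gusb (8 against 1, in SINE sequence) and Ywhaz (7 against 1).

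**Figure D4:**
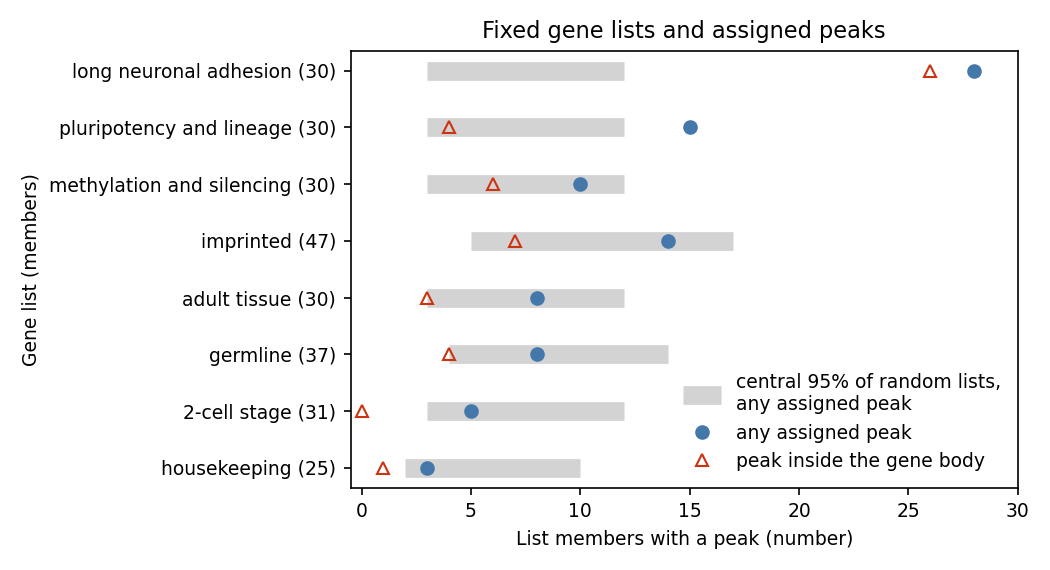
Number of members with a peak (x axis) in each gene list (y axis, members in brackets), for any assigned peak (circles) and for a peak inside the gene body (triangles). Grey bars span the central 95% of 10000 random lists for any assigned peak and apply to the circles. The circles of the long neuronal adhesion list (28 of 30) and the pluripotency and lineage list (15 of 30) lie beyond their bars. The random lists were not matched on gene length or spacing.

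Genes with many peaks were longer than genes with 1. Of the 4766 genes, 3002 had 1 peak and 190 had 5 or more. The median length was 32.1 kb for the former and 174 kb for the latter. Tenm2, named Odz2 in the file and encoding a teneurin adhesion receptor (chromosome 11, 35820171 to 36757745), had the most, with 7 peaks inside its 938 kb body and 10 outside. Cntnap5b, named C230078M14Rik in the file, followed with 15 peaks, of which 13 lay outside the body. Camta1, a calcium-responsive transcription activator gene of chromosome 4 (150433635 to 151235855), had 10 of its 11 peaks inside its body, or 12.5 per Mb. Auts2 had 11, of which 5 were inside. Car10, Adamts16, Rapgef2, Unc5d, Zfhx3 and Kirrel3 had 10 each, with 5, 2, 1, 4, 2 and 2 inside the body.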

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

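Of 151 recalculated results, 127 stayed on their side of the threshold or, where there was no test, within the main interval or spread. A further 13 moved beyond it, 5 newly passed the threshold, 4 no longer passed it, and 2 that had passed it turned in direction. Of these 2, the pluripotency and lineage list (percentile 8.82) also no longer passed. The long neuronal adhesion list (percentile 1.19) passed on the other side. Lists within the random range had no fixed direction, and several crossed an observed over expected value of 1. Merging peaks within 1 kb, planned for the peak count, left 7717 runs. Keeping 1 peak per run for the other results, peaks at a Dam-only height of 1, scaling off, promoter peaks alone, length-matched density and the first repeat named were added after the data had been seen. With peaks of height 15 or more (712 peaks), the X to autosome ratio was 0.276 and the shares became 47.6% intergenic, 44.0% gene body, 5.06% distal promoter, 3.37% proximal promoter, 20.5% SINE, 9.27% LTR and 7.16% LINE. With height 9 or more, 49.5% were intergenic and 17.9% in SINEs. The cause of these shifts was not tested, and the smaller peak sets have wider intervals. The scaled median log2 ratio was 1.05 at height 15 or more, where peaks are selected by height, and 2.17 without scaling. Within the spread between peaks, it went from 0.21 to 0.05 with 1 peak per 1 kb run, 0.10 with a pseudocount of 10, and 0.37 with height 9 or more or with heights summing to at least 10. A promoter of 5 kb on either side took in 7.56% of peaks, by its wider definition. For the pluripotency and lineage list, observed over expected members went from 2.21 to 1.14 with gene bodies alone, 1.14 with 10 kb added and 1.37 with promoter peaks alone, each within the random range, as most of its peaks are distant. The long neuronal adhesion list went from 4.12 to 1.37 with promoter peaks alone, where few genes have a peak. As peaks per Mb of body against genes with a peak, matched by length decile, these lists were at 0.578 and 0.687 of the matched mean (percentiles 8.82 and 1.19). This comparison leaves out genes without a peak, and its highest decile has no upper limit of length. The 2-cell list was at 0 with gene bodies alone (percentile 1.14), a comparison not matched on length. For its 5 members with a peak the length-matched range begins at 0, so no lower value can be shown. Differences in mean log2 height, in place of median height, were -0.0118 for intergenic peaks, 0.0364 for SINEs, -0.0857 for DNA transposons and -0.0713 for simple repeats. The medians, tied at whole numbers, do not resolve such shifts. These mean differences were not recalculated with 1 peak per 1 kb run. Merging of overlapping peaks, covered base pairs, overlap minimums, and random placement for location and repeat classes were not run, since they need peak widths or a genome of the same build. List matching on length over all genes was also not run, as lengths from another build were not used.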

Other observations

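Chemosensory receptor genes stood out among gene families that share a symbol prefix. The 5 families with at least 200 background genes were examined after the data had been seen. Olfactory receptor genes (Olfr) had a peak in 25 of 1108 members (2.26%, 1.47 to 3.31), where random lists of that size averaged 251 (central 95% 225 to 278). Of these members, 1 had a peak inside the body, against 129 expected, and 6 had one in a promoter class, against 26.9. Vomeronasal receptor genes (Vmn) had a peak in 12 of 355 members (3.38%, 1.76 to 5.83) against 80.4 expected (65 to 96), with 0 inside the body against 41.4 expected. Zinc finger genes (Zfp) had a peak in 61 of 395 members (15.4%) against 89.5 expected (74 to 106), although the highest peak of the table was assigned to 1 of them. Solute carrier genes (Slc) were within the random range for any peak (98 of 375; 85.0 expected, 70 to 101) and above it for peaks inside the body (59 against 43.7; percentile 99.2). Tmem genes were within it (53 of 238; 53.9 expected, 42 to 67). Receptor genes are short and clustered, and the random lists were not matched on length or spacing for any family. Genes absent from the submitters' annotation add to the expected numbers but could not receive a peak. The handling of multiply mapped reads is not given, and the cause of these differences was not tested.

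The tests of X copy number, of repeats on X, of chance neighbors and of the Dam-only heights were chosen after their results had been seen. X peaks were at 0.364 of the autosomal density. Peaks with no repeat were sparse on X as well, with a ratio of 0.298 (0.241 to 0.364) against 0.466 for peaks in repeats. Both ratios are per Mb of whole chromosome, and the repeat content of X and autosomes was not analysed here. Their contrast therefore cannot decide whether a loss of peaks in repeats contributes. A shortage of genes on X as the whole cause is argued against by the ratio of intergenic peaks, 0.393 (0.322 to 0.476). X copy number stays open: thinning the autosomal heights to 0.75, the X dosage of a pool with as many males as females, and applying the filter again predicted 270 X peaks (238 to 301), and thinning to 0.5, the dosage of males, predicted 92.9 (74 to 112). The 197 observed lie below the range at 0.75 and above that at 0.5, which would need a pool of males alone. For an equal pool, copy number with this filter would thus leave part of the shortfall unaccounted for. The sex ratio is not given in the labels and the thinning treats heights as reads, so the test cannot decide. No biological explanation of the X density was tested.

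Close pairs of peaks were far more frequent than chance placement gives, with 448 neighbors 70 to 200 bp apart (median gap 110 bp) against 5.56 on average (0 to 17) in 1000 random placements along the same chromosomes. A candidate explanation is a pair of read stacks from the same fragments, which were around 300 bp long. Across pairs of peaks, which are not independent replicates, the Dnmt1-Dam heights of neighbors within 200 bp correlated (Spearman 0.489, bootstrap interval 0.409 to 0.570), and those of 554 neighbors 1 to 20 kb apart did not (-0.0021, -0.084 to 0.080). If so, the 7717 runs of peaks may be closer to the number of sites than the 8226 peaks. Adjacent sites with like occupancy would give the same correlation, and no biological explanation was tested.

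Dam-only heights of 1 may include heights of 0. Among the 1652 peaks with a Dnmt1-Dam height of 12 or more, 940 had a Dam-only height of 1, 237 of 2 and 176 of 3. The ratio of the first step (3.97) to the second (1.35) was 2.95 (bootstrap interval 2.20 to 3.99), and a single negative binomial distribution of heights allows at most 1.33. That is consistent with zeros written as ones, in which case the ratios at those peaks have no upper bound. A mixture of several background distributions was not tested, nor was any biological explanation.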
